A study of Caenorhabditis elegans with 3 samples.

How the data were processed

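RNA of dissected germlines of wild-type (N2) Caenorhabditis elegans was measured in 3 libraries, which the labels place in 1 group. The germline is the reproductive tissue, which holds dividing germ cells, cells in meiosis and gametes, and the surrounding sheath and spermatheca are somatic cells. Per the labels' protocols, RNA was isolated with a column kit for small samples and libraries were made with a SMART-Seq kit for ultra low input, which copies whole transcripts from an oligo-dT primer and amplifies them by PCR. The labels name 3 numbered germline samples and do not say whether these came from separate animals or cultures, so the spread between libraries and any p-value that rests on it describe these samples and may be technical.

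The deposited values are raw read counts per gene, with a gene name and a biotype beside each gene identifier. Per the submitters' processing notes, STAR, featureCounts and the genome build WBcel235 were used. Their versions, the annotation release, the strand setting and the handling of reads that match several places are not given in the sources used here. The table holds 46739 genes, of which 20362 are protein coding, and 210 genes carry no name. Each library kept its own column. The total count was 14523486 in replicate 1, 15566299 in replicate 2 and 16656171 in replicate 3, so that 1 CPM, a count scaled to the library total, stood for 14.5, 15.6 and 16.7 reads. The limit that a count of 0 allows, 3 counts of the total, was 0.207, 0.193 and 0.18 CPM. Reads amplified by PCR without molecular identifiers are not independent molecules, so these limits cover counting error only. The intervals given below treat genes as the units and do not cover error in the counts of a gene.

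Gene positions and exon lengths were taken from the Ensembl release 115 annotation of WBcel235, the build named for the deposited counts. Of the gene identifiers, 43720 were found in the reference names and 2349 genes had another current symbol. Of the protein-coding genes, 20116 had a position and 246 had none, so the latter entered no comparison between chromosomes. Symbols below are those of the deposited table.

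The series asks which transcription factors (TFs) are expressed in the germline. With 1 group, no test between conditions exists, and the comparisons are between sets of genes within the same 3 libraries. Genes are not independent replicates, so the p-values of these comparisons describe how far a gene set stands apart from other genes in these libraries. The following choices were made before the data were examined: 21 TF families defined by gene symbol, 21 gene lists, the detection rule, the tests, most alternatives and the rule for named genes. The family definitions matched 682 protein-coding genes. They rest on symbols, so a TF with only a sequence name is missing from them. They also take in genes by symbol alone, such as the FACT histone chaperone genes hmg-3 and hmg-4. Whether each product acts as a TF was not checked. A further 11 matching symbols were pseudogenes in the table and were left out, and 4 TF genes were recognised by their current symbol only. The lists matched 387 symbols, 10 of them through the current symbol, and 3 were not matched or repeated another member (rde-3, gins-1, and atf-4 with atf-5, which are the same gene).

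CPM were computed from the deposited counts on each library's total. A gene was called detected at a CPM of at least 1 in each of the 3 libraries. Detected shares were given with 95% Wilson intervals and compared with Fisher's exact test, two-sided, with the conditional odds ratio and its 95% interval. The 17 families with at least 5 members were each compared with all other TF genes, with Benjamini-Hochberg adjustment over the 17 tests. The level of a gene list was the median over its members of the mean log2(CPM + 1), a pseudocount of 1 that compresses differences among genes of low count. Its percentile was taken among 10000 random lists of the same size from the protein-coding genes. For 9 pairs of lists, the difference of mean log2(CPM + 1) was tested with a two-sided permutation of genes (100000 resamples, Benjamini-Hochberg over the 9 pairs), whose smallest possible p is 1e-05. The spread between libraries was estimated with edgeR's common dispersion in a model with an intercept only, and libraries were compared in pairs by Pearson correlation across genes and by a chi-square of their counts.

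The rule for named genes took the 20 TFs with the highest mean CPM, the 5 detected TFs of mean CPM of at least 10 with the largest ratio between libraries, the 2 highest members of each tested family, the 3 highest members and the lowest member of each list, the 10 most abundant genes, and any member of the Hox, DREAM and germline regulator lists. Other genes named in the text were chosen after their values were seen.

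The alternatives were CPM minima of 0.5, 5 and 10, a raw count of at least 10, detection in at least 2 of the 3 libraries, edgeR's TMM factors, DESeq2 size factors, TPM from exon lengths, a pseudocount of 0.1, lists restricted to members with at least 10 counts in every library, a background of genes with at least 1 count, and leaving out each library. Library totals without rRNA genes, TFs without nuclear hormone receptors, families compared with other TFs without nuclear hormone receptors, autosomes without chromosome V, and the deposited symbols alone were added after seeing the data.

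The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0. The scripts were tested on simulated data. In counts drawn for 20362 genes from the means and totals of these libraries, 99.8% of genes with a true CPM above 2 or under 0.5 were called correctly, 5.5% of random families passed 0.05 in the exact test, and the permutation test was passed by 4% of random list pairs and by 99% of list pairs shifted by 4 log2 units. For the spread between libraries, a dispersion of 0.02 simulated over 9069 genes was recovered as 0.032 with 200 more variable genes among them, 154 of which ranked in the top 200. The dispersion estimated from the data was higher, at 0.141, and shifts shared by groups of genes were not simulated. That simulation therefore does not show how accurate the estimate is for these libraries. The counts for the detection, exact and permutation tests were also drawn with a dispersion below this estimate. The share of correct calls leaves out genes between 0.5 and 2 CPM, where the rule can fail. The random families were larger than most of the tested families.

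Some genes share reads with near-identical copies, and their counts are uncertain because the treatment of such reads is not given in the sources used here. Among the genes named, these are the major sperm protein genes, spch-1 and spch-3, the ssq genes, gsp-3 and gsp-4, puf-3 and puf-11, vit-3, vit-4 and vit-5, several col genes, hmg-3 and hmg-4, med-1 and med-2, the hsp-16 genes and the rRNA genes. Overlapping genes on opposite strands cannot be told apart for the same reason.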

Results

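The 3 libraries profiled transcripts of the dissected germline of wild-type (N2) worms, the standard laboratory strain. They held between 14523486 and 16656171 counts, of which 92.3%, 90.6% and 94.9% fell on protein-coding genes in replicates 1, 2 and 3. The 10 most abundant genes took 18.6%, 20.5% and 18.2% of the counts. The ribosomal RNA gene rrn-3.1 came first, and several of the others act in translation. The elongation factor gene eef-2 reached 24110 ± 4077 CPM (count scaled to the library total, SD, n = 3), and eef-1G, eef-1A.1, the ribosomal protein gene rpl-12 and the poly(A)-binding protein gene pab-1 followed between 9517 and 15330 CPM. The nucleoside diphosphate kinase gene ndk-1 (21310 ± 1156), the C-type lectin gene clec-87 (12330 ± 1170), the eggshell gene perm-4 (8385 ± 1109) and the mitochondrial ADP/ATP carrier gene ant-1.1 (8176 ± 709) completed the 10. A CPM of at least 1 in every library was found for 8194 protein-coding genes.

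The series set out to find which TFs are expressed in the germline. Of the 682 TF genes, 245 were detected in every library, 113 had at least 10 CPM and 18 at least 100 CPM in every library. The most abundant was ztf-7, a C2H2 zinc finger gene (WBGene00009772, chromosome V, 9786993 to 9789707), at 477 ± 52.9 CPM (SD, n = 3). It lay level with xbp-1 (WBGene00006959, chromosome III, 4193809 to 4195358), the bZIP factor of the unfolded protein response, at 473.6 ± 57 CPM, a difference smaller than the spread between libraries. Next came hmg-3 (WBGene00001973, chromosome I, 5815609 to 5818132), a subunit of the FACT histone chaperone, at 278.3 ± 22.3 CPM. The CCAAT-binding subunit gene nfyc-1 (WBGene00017742, chromosome II, 43907 to 44917) had 274.1 ± 41.3 CPM. The synMuv B zinc finger gene lin-13 (WBGene00003002, chromosome III, 7700338 to 7709491) had 247.4 ± 22.6 CPM. These positions span whole genes on WBcel235. As the families rest on gene symbols, a place in this ranking does not show that the product acts as a TF. CPM were not corrected for transcript length, and the kit copies whole transcripts. The ranking is therefore one of read counts and need not be that of transcript numbers.

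**Figure D1:**
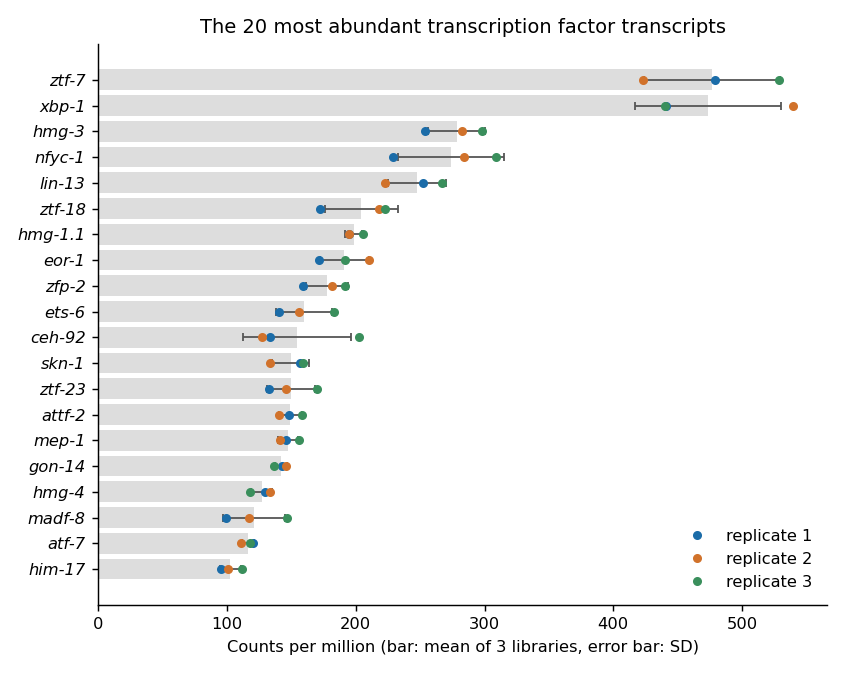
CPM (x axis) of the 20 TF genes with the highest mean. Grey bars are means and error bars SDs of 3 libraries, and points are the libraries. CPM are not corrected for transcript length. ztf-7 and xbp-1 lie at 477 and 473.6 CPM, and the other 18 between 102.6 and 278.3 CPM.

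The rest of the 20 most abundant TFs lay between 102.6 and 204.4 CPM and came from several families. The zinc finger genes ztf-18, eor-1, zfp-2, ztf-23 and mep-1 had 204.4, 191.2, 177.5, 149.4 and 147.5 CPM. The HMG box genes hmg-1.1 and hmg-4, the latter a second FACT subunit gene closely related to hmg-3, had 198.3 ± 6.58 and 127 ± 8.31 CPM. The ETS gene ets-6 had 160 ± 21.6 CPM and the homeodomain gene ceh-92 had 154.2 ± 41.9 CPM. The bZIP factors skn-1, which acts in the oxidative stress response and in early embryonic fate, and atf-7 had 149.6 ± 14.3 and 116.4 ± 4.67 CPM. The AT-hook gene attf-2, the MADF gene madf-8 and the THAP genes gon-14 and him-17, the last of which acts in meiosis, had 149.1, 120.8, 141.7 and 102.6 CPM. The libraries differed by a factor of 1.06 to 1.59 for these 20 genes, with the smallest ratio for hmg-1.1 and the largest for ceh-92.

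Among detected TFs with a mean CPM of at least 10, the libraries differed most for nhr-13 (25.5, 17.3 and 11.5 CPM in replicates 1 to 3, a ratio of 2.21) and dmd-9 (7.02, 10.8 and 14.3 CPM, a ratio of 2.04). The next were nhr-228, ceh-99 and lir-2, with ratios of 1.68, 1.66 and 1.61. No count was found in any library for 161 TF genes, and 276 had a count without meeting the rule. Of the latter, 53 reached 1 CPM in 1 or 2 libraries only.

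TF genes were detected less often than other protein-coding genes. The shares were 245 of 682 TFs (35.9%, 95% Wilson interval 32.4 to 39.6) and 7949 of 19680 other genes (40.4%, 39.7 to 41.1), an odds ratio of 0.827 (95% interval 0.703 to 0.972, Fisher's exact test, two-sided, p = 0.0191). Detected TFs were also less abundant, with a median of 10.5 CPM against 33 CPM for other detected genes, and a difference of -1.07 in mean log2(CPM + 1) (permutation test, two-sided, p = 0.0001, the smallest that 10000 resamples can give, chosen after seeing the data). The direction of the difference in detected share depended on the nuclear hormone receptors. Without them, 184 of 402 TFs (45.8%, 41 to 50.7) were detected, above the other genes (odds ratio 1.25, 1.02 to 1.53, exact p = 0.0311).

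The nuclear hormone receptors, a family that has expanded in nematodes to 280 of the 682 TF genes counted here, had the lowest detected share of the larger families. Of these, 61 were detected (21.8%, 17.4 to 27) against 184 of 402 other TFs (odds ratio 0.331, 0.23 to 0.472, exact test, adjusted p = 1.82e-09 over 17 families), and 91 had no count. The highest were nhr-49 (WBGene00003639, chromosome I, 9869651 to 9874680), a regulator of fat metabolism, at 62.7 ± 5.87 CPM and nhr-66 at 56.9 ± 3.02 CPM.

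C2H2 zinc finger genes were detected in 44 of 77 cases (57.1%, 46 to 67.6, odds ratio 2.68, adjusted p = 0.000626), bZIP genes in 17 of 28 (60.7%, 42.4 to 76.4, odds ratio 2.88, adjusted p = 0.0338) and AT-hook genes in 5 of 5 (adjusted p = 0.033), each above the other TFs (Fisher's exact test). Against other TFs without nuclear hormone receptors, a comparison added after seeing the data over 16 families, the differences kept their direction and the 3 calls were lost by the exact test. There the odds ratio was 1.76 (1.04 to 3.01, adjusted p = 0.134) for C2H2 and 1.91 (0.819 to 4.65, adjusted p = 0.273) for bZIP genes, and the 5 AT-hook genes stood against 45.1% of the others (adjusted p = 0.134, exact test). The bZIP difference was 25.9 percentage points, and its call was also lost by the exact test at 0.5 CPM (21.4 points, adjusted p = 0.0917), with a raw count of at least 10 or detection in 2 of the 3 libraries (22.2 points, 0.0884 each), without replicate 1 (24.3 points, 0.0552) and without replicate 3 (24.5 points, 0.051). The AT-hook call was lost at 10 CPM (43.8 points in place of 64.5, adjusted p = 0.0835, exact test). Examples were ztf-7 and lin-13 for C2H2, xbp-1 and skn-1 for bZIP, and attf-2 and attf-6 (91.1 ± 6.47 CPM) for AT-hook genes.

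**Figure D2:**
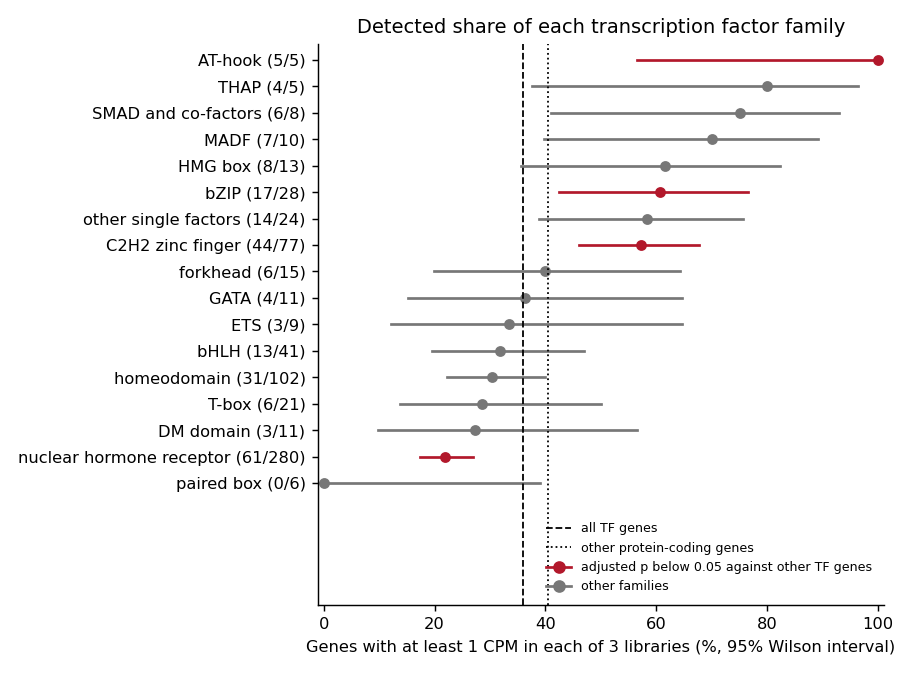
Share of each family's genes with at least 1 CPM in every library (x axis, %), with 95% Wilson intervals and detected and total genes in brackets. Red marks families that differed from all other TF genes after adjustment, from 21.8% of nuclear hormone receptors to 5 of 5 AT-hook genes. The dashed line marks all TFs (35.9%) and the dotted line other protein-coding genes (40.4%).

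Homeodomain genes, many of which set cell identity along the body and in the nervous system, were detected in 31 of 102 cases (30.4%, 22.3 to 39.9). They did not differ from all other TFs (odds ratio 0.747, exact test, adjusted p = 0.34). Against TFs without nuclear hormone receptors they were detected less often (odds ratio 0.42, 0.251 to 0.693, exact test, adjusted p = 0.00548). After ceh-92, the highest was ceh-44 (83 ± 5.63 CPM), which the current reference lists as cone-1. Counts per gene do not tell its transcripts apart, so this value need not stand for transcripts that encode the homeodomain. bHLH genes were detected in 13 of 41 cases, led by the Max-like genes mxl-1 (52 ± 10.5 CPM) and mxl-2 (50.1 ± 2.94 CPM). T-box genes were detected in 6 of 21, led by tbx-36 (23.3 ± 4.12 CPM) and tbx-9 (13 ± 1.07 CPM). None of the 6 paired box genes was detected, with the highest, npax-4, at 0.109 CPM, and the family did not pass the test (adjusted p = 0.158, exact).

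The other families did not pass the adjusted exact test, with values between 0.0809 and 1. HMG box genes were detected in 8 of 13 cases, THAP genes in 4 of 5 and MADF genes in 7 of 10, with madf-6 at 67.2 ± 9.04 CPM. SMAD genes and their co-factors, the output of TGF-beta signalling, were detected in 6 of 8, led by the X-linked sma-9 (22.7 ± 1.25 CPM) and daf-3 (9.71 ± 0.377 CPM). Forkhead genes were detected in 6 of 15, with the insulin pathway factor daf-16 at 56.9 ± 3.22 CPM and the gonadal factor fkh-6 at 8.68 ± 1.02 CPM. The ETS family was represented by 3 of 9 genes, and ets-6 stood far above the second, ets-5 (3.12 ± 0.757 CPM). GATA factors were detected in 4 of 11, led by egl-18 (11.9 ± 2.53 CPM), and DM domain genes in 3 of 11, led by dmd-9. The set of single factors was detected in 14 of 24 cases, led by snpc-4 (100.4 ± 5.39 CPM), which acts at piRNA genes, and let-526 (92.9 ± 4.35 CPM). In the families too small to test, all 4 E2F/DP genes, all 4 NF-Y genes, 3 of 4 FLYWCH genes and 2 of 4 SAND genes were detected.

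The X chromosome, which is known to be largely silenced during much of germ cell development, held fewer detected genes. Of X-linked protein-coding genes, 900 of 2742 (32.8%, 31.1 to 34.6) were detected against 7256 of 17362 autosomal genes (41.8%, 41.1 to 42.5), an odds ratio of 0.681 (0.624 to 0.742, Fisher's exact test, two-sided, p = 2.9e-19). Chromosome V had a lower share still, 1204 of 5075 genes (23.7%), while chromosomes I and III had 57.9% and 58.4%. For TF genes, 36 of 114 on X (31.6%, 23.8 to 40.6) and 209 of 566 on autosomes (36.9%, 33 to 41) were detected, which did not differ at this number of genes (odds ratio 0.789, 0.497 to 1.23, exact p = 0.287). The TF difference passed the test when only genes of at least 10 CPM in every library were counted (odds ratio 0.486, exact p = 0.0275). It also passed without nuclear hormone receptors (27 of 85 against 157 of 316, odds ratio 0.472, exact p = 0.0033), a choice made after seeing the data.

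**Figure D3:**
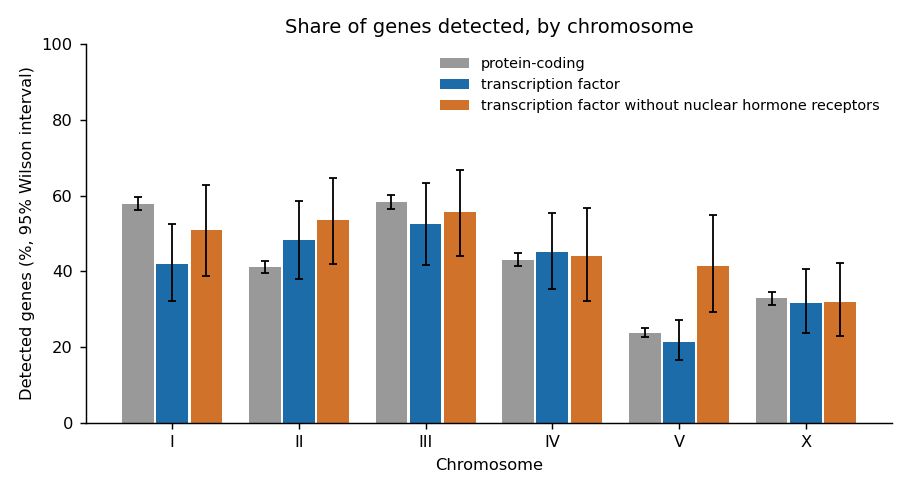
Share of genes detected in every library (y axis, %) on each chromosome (x axis), with 95% Wilson intervals, for all protein-coding genes, TF genes and TF genes without nuclear hormone receptors. Among all protein-coding genes the share was lowest on V (23.7%) and X (32.8%) and highest on III (58.4%).

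Genes of the germline itself were abundant. All 25 oocyte and eggshell genes were detected, with a list median of 8.92 in log2(CPM + 1) (SD of the library medians 0.08, n = 3), above all 10000 random lists. The permeability barrier genes perm-4 (WBGene00016638, chromosome IV, 1121494 to 1125107) and perm-2 and the yolk receptor gene rme-2 had 8385, 5951 and 5049 CPM, and the lowest member, the meiotic spindle gene mei-2, had 102 CPM. All 25 germ granule and small RNA genes were detected (median 7.71, SD 0.07), led by the RNA helicase genes cgh-1 (2055 ± 407 CPM) and glh-1 (1684 ± 490 CPM). All 16 genes of the germline stem cell and mitotic zone list were detected (median 7.59, SD 0.09), with the PUF genes puf-3 and puf-11 at 546.7 ± 17.1 and 461 ± 24.3 CPM and sygl-1, a Notch target in germline stem cells, at 411.7 CPM. All 39 meiotic prophase genes were detected (median 5.83, SD 0.13), among them lab-1 (352.9 ± 77.2 CPM), the synaptonemal complex gene syp-4 (323.5 ± 27.6 CPM) and spo-11 (206.5 ± 44 CPM), which makes meiotic double-strand breaks. These last 3 lists also lay above all random lists.

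Spermatogenesis genes were lower and differed between libraries. Of 32 genes, 21 were detected, and the list median was 4.26, with 4.29, 2.48 and 4.49 in replicates 1, 2 and 3. The sperm genes ssq-4, ssq-1 and ssq-2 had means of 553, 427.7 and 376.8 CPM, with ssq-4 (WBGene00006053, chromosome IV, 5016479 to 5017766) at 1177, 140.9 and 340.5 CPM in the 3 libraries. The list lay 5.07 log2 units below the oocyte and eggshell list (3.96, 6.38 and 4.87 in replicates 1 to 3, permutation test, two-sided, adjusted p = 1.29e-05 over 9 pairs, from the smallest p that the resamples can give). In log2(CPM + 1), 27 of the 32 genes were at least 2-fold lower in replicate 2 than in replicate 1, among them the sperm fate gene fog-3 (1.45, 0.129 and 1.44 CPM). The other 5 were the TF gene spe-44 (25.8, 27.2 and 35.1 CPM), the translational regulator gene fog-1 (18, 25.7 and 23.7 CPM), spe-6 (16.7, 18.4 and 22.1 CPM), and spe-29 and spe-42, which stayed under 1 CPM in every library. This count was chosen after seeing the data. Adult cuticle collagens such as col-140 were also lowest in replicate 2 and highest in replicate 1 (423.7, 30.4 and 84.6 CPM for col-140), and replicate 2 also had the highest rRNA share (9.04%) and the highest level of all 12 mitochondrial genes.

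**Figure D4:**
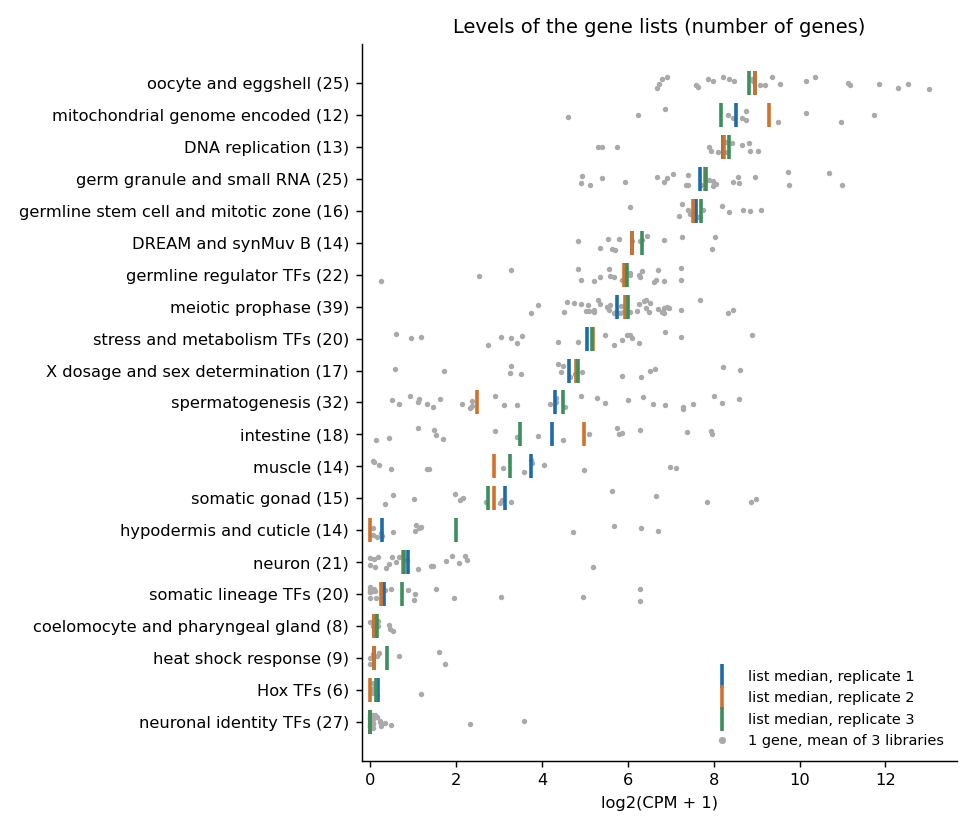
Levels in log2(CPM + 1) (x axis) of the 21 gene lists, with the number of genes in brackets. Grey points are genes (mean of 3 libraries) and coloured ticks the list medians in each library. The oocyte and eggshell list has the highest median (8.92), the neuronal identity TFs the lowest (0.05), and the ticks of the spermatogenesis list lie between 2.48 and 4.49.

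TFs with known roles in the germline stood far above TFs of somatic fates. Of 22 germline regulators, 21 were detected, with a list median of 5.95 (SD 0.04). Besides skn-1 and attf-2 they included xnd-1 (113.8 ± 1.92 CPM) and snpc-4. The pairing centre proteins him-8, zim-1, zim-2 and zim-3 had 50.4, 46.8, 37 and 46.2 CPM. The Notch effector lag-1 had 64.8 ± 3.31 CPM, the p53 homologue cep-1 76.7 ± 10.6 CPM, hsf-1 65.3 ± 0.328 CPM and lsl-1 96.7 ± 8.71 CPM. The sex determination factor tra-1 (8.66 ± 0.383 CPM) and the GATA factor elt-1 (5.08 ± 2.31 CPM) were lower, and nhr-25 was not detected, at 0.19 CPM. All 14 DREAM and synMuv B genes, which repress germline and cell cycle genes in the soma, were detected (median 6.19, SD 0.13), from efl-1 (27.5 ± 0.639 CPM) to lin-53 (259.2 ± 3.11 CPM). Other members were met-2 (154 ± 22.2 CPM), lin-9 (114 ± 7.05 CPM) and lin-35 (48.6 ± 5.4 CPM). This list does not hold TFs only, as lin-53 and met-2 are not in the TF families.

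Of 27 neuronal identity TFs, only 2 were detected, the LIM homeodomain genes lim-6 (11.1 ± 1.87 CPM) and lin-11 (4.2 ± 1.87 CPM), and 10 had no count in any library. The list median of 0.05 lay at percentile 0.52 of the random lists. The germline regulators exceeded it by 5.21 log2 units (SD 0.04, n = 3 libraries) and the DREAM list exceeded it by 5.99 (SD 0.08), both with adjusted p = 1.29e-05 by permutation. The germline regulator and DREAM lists share efl-1, dpl-1, lin-54 and lin-15B, so these differences are not independent. Of 6 Hox genes, which pattern the body axis, lin-39 alone was detected, at 1.29 ± 0.343 CPM, and the others had means between 0.023 and 0.126 CPM, with at most 4 counts in a library. TFs that specify somatic lineages were detected in 6 of 20 cases and lay 4.10 log2 units below the germline regulators (SD 0.02, adjusted p = 1.29e-05 by permutation). The 6 included the caudal homologue pal-1 (77.6 ± 9.94 CPM), lin-26 (76.5 ± 6.23 CPM) and nhr-23 (30.4 ± 3.32 CPM). In contrast, the endoderm genes med-1 and med-2, which are near-identical copies, and tbx-35 had no count.

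Stress and metabolism TFs were detected in 17 of 20 cases (median 5.15, SD 0.07), led by xbp-1, skn-1 and atf-7, with pqm-1 the lowest at 0.52 CPM. Of 9 heat shock response genes, 1 was detected, hsp-70 at 2.44 ± 0.85 CPM, and hsp-16.41 had 2.21 ± 1.19 CPM. The hsp-16 genes are near-identical copies whose reads may not have been counted, so a low value for them cannot be read as low expression. Genes of X dosage compensation and sex determination were detected in 16 of 17 cases (median 4.64, SD 0.11), led by mix-1 (395.6 ± 83.3 CPM), fem-1 (295.2 ± 21.4 CPM) and tra-2 (97.47 ± 1.128 CPM). The male-determining switch gene xol-1 was the exception at 0.52 CPM. All 13 DNA replication genes were detected (median 8.28, SD 0.08), with rnr-1, mcm-7 and rnr-2 at 525.8, 456.2 and 454.9 CPM. All 12 genes of the mitochondrial genome were detected (median 8.70, SD 0.57), and all 12 were highest in replicate 2, with ctc-1 at 3219, 4730 and 2578 CPM.

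Somatic transcripts were present at lower levels than the pooled germline lists, but several of their lists were not low among all protein-coding genes. The intestine, muscle and somatic gonad medians lay at percentiles 99.28, 95.64 and 93.88 of the random lists. The hypodermis and neuron medians lay at 62.59 and 54.87. The intestine median (4.20) was close to that of the spermatogenesis list (4.26). The germline lists, pooled to 136 genes, exceeded the somatic gonad list by 2.77 log2 units (SD 0.18, n = 3, adjusted p = 0.0001), the intestine list by 2.58 (SD 0.92, adjusted p = 7.87e-05), and the muscle, hypodermis and neuron lists by 3.73, 4.56 and 5.51 (each with adjusted p = 1.29e-05), all by permutation over 9 pairs. In the somatic gonad list, which covers sheath, spermatheca and distal tip cells, 12 of 15 genes were detected. Among them were the collagen IV gene let-2 (515.7 ± 138 CPM), filamin fln-1 (470.6 ± 78.2 CPM) and the sheath gap junction gene inx-8 (232.5 ± 61.1 CPM), while lag-2, the distal tip cell ligand, had 0.287 CPM. The muscle list was detected in 9 of 14 cases, led by unc-54 (142 ± 43 CPM) and unc-15 (129.4 ± 41.6 CPM), with the pharyngeal myosin gene myo-2 at 0.04 CPM. Of 21 neuron genes, 7 were detected, with snb-1 (35.3 ± 1.61 CPM) far above unc-31 (3.83 ± 1.17 CPM) and ric-4 (3.72 ± 1.14 CPM). None of the 8 coelomocyte and pharyngeal gland genes was detected.

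The intestine list was detected in 14 of 18 cases, with medians of 4.24, 4.98 and 3.48 in replicates 1, 2 and 3. It was led by the vitellogenin genes vit-6 (108.5, 516.8 and 266.7 CPM), vit-2 (116.2, 483.6 and 255.5 CPM) and vit-5 (84.2, 590.4 and 88.2 CPM), which encode yolk proteins, while the intestinal GATA factor elt-2 had 0.106 CPM. Replicate 2 also had the highest share of rRNA (7.24%, 9.04% and 4.61% in replicates 1 to 3) and the highest level of all 12 mitochondrial genes. The hypodermis and cuticle list was detected in 4 of 14 cases, all of them collagens, with col-140 at 423.7, 30.4 and 84.6 CPM, col-124 at 401.1, 17.6 and 64 CPM and col-119 at 159.3, 16.06 and 47.43 CPM. With only members of at least 10 counts in every library, these collagens alone were left and the germline lists exceeded them by 1.102 log2 units, which did not pass the test (adjusted p = 0.305, permutation).

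The counts of the libraries differed by more than sampling noise, as separately amplified libraries of 1 RNA sample also would, with a chi-square per degree of freedom of 107.1, 65.5 and 85.8 for replicates 1 and 2, 1 and 3, and 2 and 3. Across 9428 genes, which are not independent replicates, Pearson's r of log2(CPM + 1) was 0.912, 0.969 and 0.951 for these pairs. A difference of over 2-fold was found for 1481, 841 and 1441 of these genes. Among TF genes it was found for 3, 5 and 4, and r was 0.985, 0.982 and 0.984. Among genes detected in every library, the median coefficient of variation was close for TFs (13.1%) and other genes (13.6%). These medians do not reflect the genes that differed most. The biological coefficient of variation from edgeR's common dispersion was 37.6%, and 28.2% without replicate 2. Several gene groups differed between the libraries. Major sperm protein genes took 2.87%, 0.348% and 0.923% of the counts, and 30 of the 30 that reached 1 CPM were highest in replicate 1. Cuticle collagens took 0.369%, 0.035% and 0.0782%, and of the 75 that reached 1 CPM, 44 were highest in replicate 1, 3 in replicate 2 and 28 in replicate 3. All 6 vitellogenin genes were highest in replicate 2, at 0.0429%, 0.237% and 0.0681%. These 3 groups were chosen after seeing the data.

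**Figure D5:**
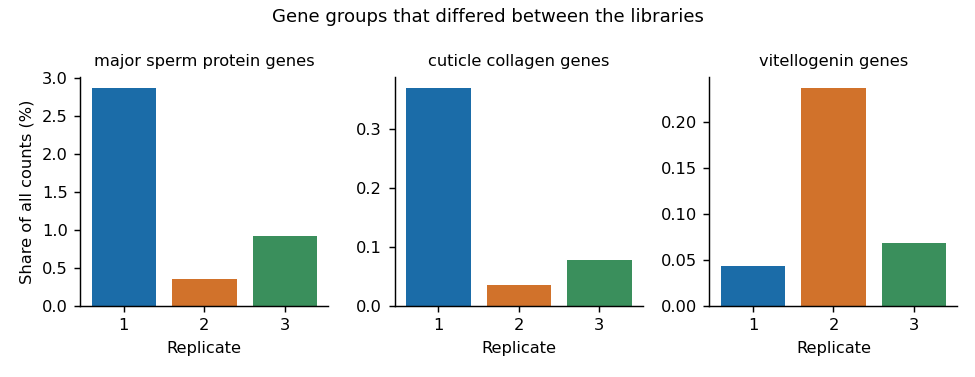
Share of all counts (y axis, %, a separate scale in each panel, from 0) taken by major sperm protein, cuticle collagen and vitellogenin genes in each library (x axis). Each bar is 1 library. The sperm and collagen shares are highest in replicate 1 (2.87% and 0.369%) and the vitellogenin share in replicate 2 (0.237%).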

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

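No test in this part was chosen after the result was seen, as the values are shares of counts. The count table also holds genes outside the protein-coding set, which none of the comparisons between gene sets used. With no control samples, each class is given here because its counts exceeded the limit that a count of 0 allows in every library. Ribosomal RNA genes took 6.96% of the counts (mean of 3 libraries), most of it on rrn-3.1, and pseudogenes took 0.351%, led by F54D7.7 at 809.7 CPM. Other non-coding RNA genes took 0.0539%, led by C36C9.10 at 122.3 CPM, and lincRNA genes 0.0264%, led by linc-7 at 226.2 CPM. The snoRNA and snRNA genes took 0.0091% and 0.00272%. The remaining classes took smaller shares still, with 0.000576% on piRNA genes, 0.000384% on antisense genes, 0.000221% on miRNA genes and 0.00015% on tRNA genes. The kit primes on poly(A) tails, so the low shares of small and unpolyadenylated RNA say nothing of their level in the germline.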

How the results depend on the processing

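The tests with rRNA-free totals, without nuclear hormone receptors, without chromosome V and with deposited symbols only were chosen only after the result was seen. The count of detected TFs was 155 at 5 CPM and 113 at 10 CPM against 245 at 1 CPM, by construction of the stricter rule, and lay between 223 and 274 under the other minima, scalings, symbols and sets of libraries, all families kept. TFs remained below other genes in detected share under every scaling, minimum and set of libraries. Without nuclear hormone receptors, the odds ratio was 1.25 in place of 0.827, because 280 of the 682 genes leave the set. The X-linked share of TFs passed the test at 10 CPM (odds ratio 0.486), without nuclear hormone receptors (0.472) and against chromosomes I to IV (0.525). For all protein-coding genes, the X-linked odds ratio was 0.522 at 5 CPM and 0.371 at 10 CPM in place of 0.681 at 1 CPM. The number of families above all other TFs was 5 at 5 CPM and 5 at 10 CPM in place of 3, and 0 against other TFs without nuclear hormone receptors. For the stricter minima the cause was not tested.

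Of 220 family values under alternatives, 183 kept direction and side of the threshold, 9 lost and 12 gained the call, and 16 turned direction, all in families without a call in either setting. As percentage points against the other TFs, GATA genes lay at -3.88, -13.9 and -16.8 with 0.5, 5 and 10 CPM, at -3.13 with 10 reads, at -5.51 with TPM, at -0.447 without rRNA in the totals, at -9.67 against TFs without nuclear hormone receptors, and at -1.04, 8.94 and -0.894 without replicate 1, 2 or 3. Forkhead genes lay at -2.79 and -10.1 with 5 and 10 CPM, -6.17 with TPM and -5.99 against TFs without nuclear hormone receptors. Calls were gained by SMAD genes, THAP genes, HMG box genes and the single factors under other minima, TPM, rRNA-free totals, detection in 2 libraries or without replicate 3, and by homeodomain genes against TFs without nuclear hormone receptors. The bHLH genes lay at 1.77 with 5 CPM and 1.54 with TPM, and SMAD genes at -4.12 with 10 CPM. The cause was not tested.

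Of 79 differences between lists under alternatives, 78 kept direction and call. The exception was germline minus hypodermis with low members left out (1.102), where few genes were left. That filter left too few neuronal identity TFs for 2 of the pairs. The coefficient of variation was between 28.2% and 45.6% with 1 library left out. Of 188 list medians, 46 moved by more than the spread between libraries, most with TPM, a pseudocount of 0.1 or the filter. At these depths a gene under about 0.2 CPM cannot be told from absent.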

Other observations

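In this part, the tests of library scaling, of spermatheca and sheath tissue, of muscle tissue and of chromosome V were chosen only after the result was seen, and so were the gene groups. The 30 proteasome subunit genes were all detected and took 0.806%, 0.815% and 0.803% of the counts in replicates 1 to 3. Ribosomal protein genes took 10.3%, 9.43% and 11.1%, with 75 of 76 detected. Histone genes, most of whose transcripts lack poly(A) tails, took 0.124% on average, with 34 of 72 detected.

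Other transcripts set single libraries apart. The larval cuticle collagen genes dpy-13, dpy-4 and sqt-3 had 9.07, 8.4 and 4.74 CPM in replicate 3 and at most 0.321 CPM in replicates 1 and 2. The amino acid metabolism genes pah-1 and haly-1 had 17.9 and 15.9 CPM in replicate 1 and at most 1.5 CPM in the others. These 5 genes were chosen after their values were seen, and pah-1 and haly-1 were not among the epidermal genes compared below.

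Spermatogenesis transcripts differed between libraries, with a median log2 ratio of replicate 2 to replicate 1 of -2.65 over the 32 spermatogenesis genes (95% bootstrap interval -2.943 to -1.996), and 27 of the 32 at least 2-fold lower, while cuticle collagens (0.369%, 0.035% and 0.0782% of the counts) were also lowest in replicate 2, which had the highest rRNA share (9.04%). The tables argue against scaling as the whole cause, since the lowest ratio between the highest and lowest library under TMM factors, DESeq2 factors or totals without rRNA was 4.71, against 4.84 on the library total. Different amounts of spermatheca and sheath tissue would have moved their genes alike, but 13 such genes had a median of -0.21 (-0.54 to 0.29), with 2 of them at least 2-fold lower. As these 13 genes pool both tissues, their median cannot show whether the amount of spermatheca alone differed. A hypothesis that stays open and untested is that the animals differed in age or in remaining sperm, for which the labels give no value, so no biological explanation was tested.

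Adult cuticle collagens such as col-140 were highest in replicate 1, and carry-over of epidermis is a candidate explanation. The 11 epidermal genes other than collagens with enough counts had a median log2 ratio of replicate 1 to the others of 0.31 (-0.08 to 0.59), under the bound of 1 set in advance. This result cannot decide the question, because only 3 of the 11 reached 5 CPM in any library and the pseudocount shrinks the ratios of the others. The 3 were nlp-31 (5.85, 0.514 and 1.26 CPM), mlt-10 (4.13, 6.3 and 2.58 CPM) and far-2 (648.6, 622.8 and 776.9 CPM), whose baseline would hide a small share. As nlp-31 passed 5 CPM only in replicate 1 and mlt-10 only in replicate 2, no conclusion is drawn from their directions. Muscle carried over with the body wall cannot be told apart either, as 10 muscle genes had a median of 0.69 (0.52 to 1.17), an interval that includes the bound of 1, and gonadal sheath cells express several of these genes. No biological explanation was tested.

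Yolk and several other intestinal transcripts were highest in replicate 2, which also had the highest shares of rRNA (7.24%, 9.04% and 4.61%) and mitochondrial transcripts, and carry-over of intestine may account for the yolk group. The 23 other intestinal genes had a median log2 ratio of replicate 2 to the others of 0.37 (0.26 to 0.66), under the bound of 1 set in advance, but 11 of them stayed under 5 CPM in every library, where the pseudocount shrinks ratios. The 12 that reached 5 CPM in any library had a median of 0.58 (0.26 to 1.15). A rise in replicate 2 can itself bring a gene over 5 CPM, as for spp-3 (2.27, 7.32 and 1.86 CPM), so this subset cannot decide the question. Of the 12, 6 changed at least 2-fold: spp-5 (4.06, 11.4 and 1.2 CPM), sodh-1, dod-19, lys-1 and spp-3 upward and acs-2 (2.89, 1.48 and 8.04 CPM) downward. Of the others, lbp-6 (23.4, 15.2 and 20 CPM) was also lowest in replicate 2 and clec-63 highest in replicate 1. In the intestine list, which includes the vitellogenin genes that set the pattern, 16 genes had a median of 1.42 (-0.17 to 2.16). Of these, 10 were at least 2-fold higher and 1 at least 2-fold lower in replicate 2. Carry-over thus cannot be told apart from other sources. Scaling does not account for the pattern, with a lowest ratio of 2.37 between libraries under the other scalings against 2.28 on the library total. No biological explanation was tested.

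As a separate hypothesis, the low detected share of nuclear hormone receptors was set against their position, since 167 of the 280 lie on chromosome V, which had the lowest share of all chromosomes. If location on chromosome V were the whole cause, receptors elsewhere would be detected as often as other TFs. Outside chromosome V, 36 of 113 receptors (31.9%) and 162 of 349 other TFs (46.4%) were detected, an odds ratio of 0.54 (0.334 to 0.862, Fisher's exact test, two-sided, p = 0.0085), so location on chromosome V alone does not account for the difference. On chromosome V the odds ratio was 0.25 (0.118 to 0.529), with 25 of 167 receptors and 22 of 53 other TFs detected, and the difference between these odds ratios was not tested. The gap was not seen on every chromosome. Receptors were detected less often than other TFs on I (20% against 50.8%), II (25% against 53.5%) and III (25% against 55.7%). On IV (47.1% against 44.1%) and X (31% against 31.8%) they were level with other TFs. Each of these chromosomes holds only 8 to 34 receptors, and position within a chromosome was not tested.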
